A study of Gallus gallus with 66 samples.

How the data were processed

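The series measured RNA of chicken caecum, the blind gut pouch that the coccidian parasite Eimeria tenella infects, together with RNA of the parasite. The labels give 66 sequencing runs of 36 birds. Of these birds, 30 were sequenced in 2 runs and 6 in 1 run. Every bird is labelled as infected, and no uninfected birds are among the samples. RNA was extracted with TRIzol and chloroform, and libraries were made with a stranded mRNA kit with polyA selection. The labels give days 1, 2, 3, 4 and 10, whereas the series describes 6 time points with 6 replicates each. At day 3 there are 12 birds, and each replicate number from 1 to 6 is used 2 times. Whether some of the day 3 birds belong to another time point cannot be told from the labels, so they were kept apart by sequencing.

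The names of the runs place the birds in 3 run sets, called A, B and C here. Run set A holds replicates 2 to 6 of day 2, day 4 and 5 of the day 3 birds. Run set B holds replicates 2 to 6 of day 1, day 10 and 5 other day 3 birds. Run set C holds replicate 1 of each day, with 2 birds at day 3. The 7 groups were therefore day 1 (6 birds), day 2 (6), day 3 of run set A (5), day 3 of run set B (5), day 3 of run set C (2), day 4 (6) and day 10 (6). The groups, the main tests, the gene lists and the rule for naming genes were fixed before the data were examined. Alternatives, tests and named genes chosen later are marked as such.

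The deposited values are raw counts per chicken gene and per parasite gene for each sequencing run, which the authors did not normalise. Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.7.2b, HTSeq 0.9.1 and edgeR were used with the chicken build GRCg6a; the settings, the annotations and the parasite build are not stated. Every value was a whole number, and each of the run columns matched a label, with 0 unmatched. There were 24390 chicken genes and 7311 parasite genes. Gene biotypes came from a RefSeq gene table of the later assembly GRCg7b, used for names and biotypes only, which matched 19810 of the chicken identifiers (81.2%). No coordinates are given, because the assembly of the counts was not used here.

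Counts of repeat runs were summed per bird. Each first run was most correlated with the second run of its own bird in 30 of 30 birds, and the same held for the second runs, over the genes with a mean of at least 10 CPM (counts scaled to a common library size). Summed chicken counts per bird were 297258242 to 488906810 in run set A, 24398061 to 100968382 in run set B and 242606657 to 471879152 in run set C. Repeat runs differed by more than counting error in run set A, where chi-square per degree of freedom was 26 to 319, and by little more than counting error in run set B, where it was 1.31 to 1.57. Genes of ribosomal RNA took 3.69% to 62.7% of a bird's counts, most of them in the single gene LOC112533599, and they stayed in the counts. The first principal component held 21.2% of the variance of log CPM and had a Pearson correlation of 0.73 with the ribosomal RNA percent.

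Differential expression was tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit, glmQLFTest), in a single fit of all 36 birds with group and run set as terms. Genes were filtered with filterByExpr by group, which left 19243 genes, and TMM normalisation was used. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. All p-values are two-sided. Of the 9 comparisons, 6 set groups that share run set A or B against each other. The others cross run sets: day 2 against day 1, day 10 against day 4 and the day 3 sets of A and B. Only the single birds of days 1, 2, 4 and 10 in run set C bridge these. The day 3 birds of run set C form their own group and do not. CPM values in the text are TMM-normalised means over the birds of a group with their SD, so that a fitted fold change can differ from the ratio of the means. For the fits, the median standard error of the log2 fold change over the 8494 genes with a mean of at least 10 CPM was 0.179 for day 4 against day 2, 0.181 for day 10 against day 1, 0.336 for day 2 against day 1 and 0.393 for the 2 day 3 sets.

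The tests were run on simulated data with 200 changed genes, of which 100 changed 2-fold and 100 changed 4-fold. The changed genes were drawn from those with an average over 10 CPM, so the recovery does not cover lower genes. Each gene was simulated independently, so the false calls do not reflect structure shared by genes, such as that of ribosomal RNA. The adjustment over all genes is also milder with 200 changed genes than in a comparison with few. Recovery can be lower in such a comparison, so few or no calls do not show that 2-fold changes are absent. At 2-fold and 4-fold the test recovered 83% and 98% for day 4 against day 2, 85% and 98% for day 10 against day 1, 79% and 99% for day 3 of run set A against day 2, and 76% and 99% for day 3 of run set B against day 1. For the cross-run comparisons, recovery was 19% and 84% for day 10 against day 4 and 15% and 79% for day 2 against day 1. False calls were 2.14% to 4.08% of all calls. The remaining comparisons were not simulated.

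Gene lists, 27 in number, covered interferon responses, cytokines, immune cell types, epithelial cell types, metabolism, antigen presentation and other tissues of the gut wall. Each list with at least 5 tested members was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and adjusted over the 27 lists within a comparison. Camera with a correlation estimated for each list and the self-contained test fry were run beside it. With an estimated correlation, 0 lists passed in any comparison, and 0 passed with fry, so every list result below rests on the preset correlation. Members were also counted as called when adjusted over the list alone.

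The named genes followed a fixed rule. It takes up to 5 genes with a symbol each way, which leaves out LOC identifiers, with the largest fold change among called genes with an absolute log2 fold change of at least 1 and a mean of at least 10 CPM. It adds the 3 members with the smallest p of up to 6 lists that passed. In 4 comparisons it adds 13 genes of immunity, epithelium and proliferation, whatever their p. Called genes outside that rule were named because the counts were small, after their values were seen. Reads shared between near-identical members of the GBP, very large interferon-inducible GTPase and CC chemokine families cannot be separated in these counts, so values of such genes are uncertain in that respect.

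The labels do not say that equal replicate numbers mark related birds. For each comparison, the deviation of each bird of replicates 2 to 6 from its group mean was correlated between birds of equal number. All 5 pairs of day 3 of run set B and day 1 were correlated by more than 0.1 (0.24 to 0.77), and in no other comparison was that so for all 5 pairs. The numbers were therefore read as pairing birds in that comparison alone, and the fit with replicate number as a block is given beside it. The block gives each number an effect common to all groups, so it does not model the pairs of that comparison alone. The gene set and the definition of the deviation of this check were revised after a first version, in which the same 5 pairs also passed.

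The parasite share is the sum of parasite counts over the sum of parasite and chicken counts of a bird. It was compared on the log2 scale, with 0.5 added to the parasite count, by exact permutation of the birds between groups, adjusted over the 9 comparisons; intervals on single birds are Wilson intervals at 95% and cover counting error only. Tests of single parasite genes and of chicken genes against parasite load required a group median of at least 10000 parasite counts. The largest group median was 847, so these tests and their alternatives were not run.

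Alternatives chosen in advance were DESeq2 1.42.0 in place of edgeR, RLE size factors, 2 other filters on low counts, no run set term, replicate number as a block, run set C left out, the first run of each bird alone, a fit of the 2 compared groups alone, all 12 day 3 birds as a single group, and each bird left out in turn. Alternatives added after the data were seen were ribosomal RNA genes left out, the ribosomal RNA percent as a covariate, birds with over 50% ribosomal RNA left out, a surrogate variable from sva 3.50.0, a robust fit, the leading parasite gene left out, and each bird left out in the list tests. The value of 1 member of the gene lists is not reported here, and it remained in the list tests. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.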

Results

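RNA of the caecum was counted in 36 chickens labelled as infected with Eimeria tenella, 6 each at days 1, 2, 4 and 10 and 12 at day 3. The day 3 birds were treated as 3 groups by the run set in which they were sequenced, with 5 birds in run set A, 5 in run set B and 2 in run set C. Chicken gene counts per bird ranged from 30466787 to 273017254 at day 1 and from 301446692 to 488906810 at day 2. They were 329612047 to 404190921 at day 4 and 24398061 to 242606657 at day 10. At day 3 they were 297258242 to 416972497 in run set A, 32462218 to 46412150 in run set B and 289097994 to 360412859 in run set C. Genes of ribosomal RNA, which polyA selection is meant to remove, took 30.0% ± 13.3 of the counts at day 1 (SD, n = 6) and 37.0% ± 5.24 at day 2. They took 35.6% ± 13.6 at day 4 and 44.0% ± 19.2 at day 10. The bird of run set C was the lowest at days 1, 4 and 10, at 5.17%, 14.7% and 7.89%. The other birds averaged 34.9% ± 6.05, 39.8% ± 9.96 and 51.2% ± 8.31 on these days (n = 5 each). At day 3 ribosomal RNA genes took 41.4% ± 8.88 in run set A (n = 5), 33.1% ± 6.11 in run set B (n = 5) and 6.37% ± 3.79 in run set C (n = 2). Within run set B the day 10 birds, at 44.2% to 62.7%, did not overlap the day 1 birds, at 25.2% to 41.5%.

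**Figure D1:**
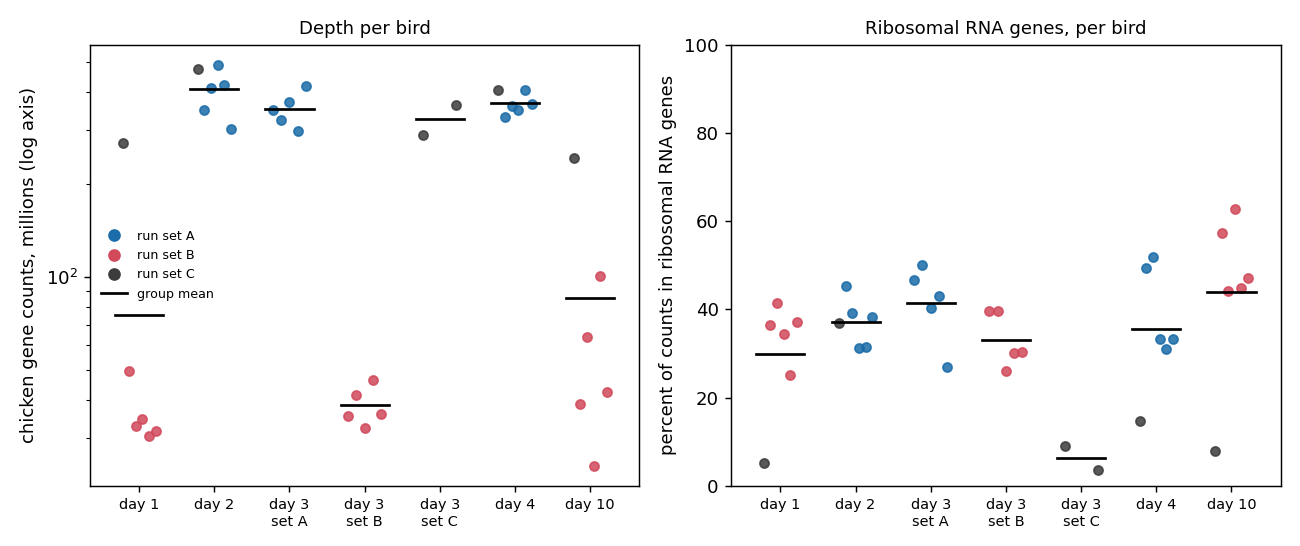
Chicken gene counts per bird (left, log axis) and percent of counts in ribosomal RNA genes (right) for the 7 groups, with points for birds coloured by run set and bars for group means. Birds of run set B lie between 24398061 and 100968382 counts, and those of run sets A and C at 242606657 or more.

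The parasite was almost absent from the counts. All 66 runs together held 11332 parasite counts, in 695 of the 7311 parasite genes, and a bird held 18 to 1955 of them. A single gene, ETH2_1412500, took 6052 of these counts (53.4%) and had a count in all 36 birds, and the 4 leading genes together took 73%. Parasite counts as CPM of all gene counts of the bird averaged 1.49 ± 0.785 at day 1 (SD, n = 6) and 1.57 ± 1.32 at day 2 (n = 6). They averaged 0.964 ± 0.514 at day 4 (n = 6) and 1.51 ± 0.532 at day 10 (n = 6). At day 3 they averaged 0.999 ± 0.0711 in run set A (n = 5), 2.32 ± 1.35 in run set B (n = 5) and 2.51 ± 1.27 in run set C (n = 2).

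None of the 9 comparisons of the parasite share passed after adjustment. From day 2 to day 4, when the parasite multiplies in the epithelium in a typical infection, the mean log2 share differed by -0.53 (exact permutation p = 0.323, adjusted p = 0.581), and by -0.19 without day 2 replicate 1. The largest difference was between the day 3 birds of run sets A and B, at -1.01 (exact permutation p = 0.0476, adjusted p = 0.429). Day 10 and day 1 differed by 0.09 (exact permutation p = 0.818, adjusted p = 0.881). With 18 to 332 counts per bird at day 1 and 31 to 184 at day 10, no group reached the depth set in advance for tests of single parasite genes, and these were not run.

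**Figure D2:**
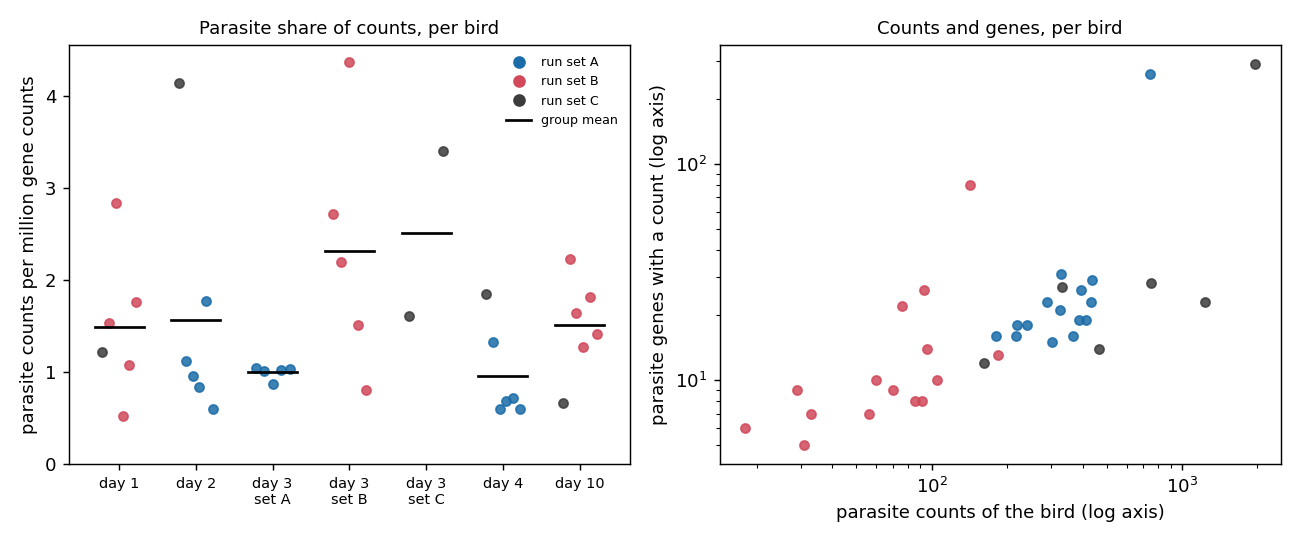
Parasite counts as CPM of all gene counts, per bird and group (left; bars are group means) and the number of parasite genes with a count against the parasite counts of the bird (right, both axes log). Points are coloured by run set. CPM values lie between 0.521 and 4.37, and day 2 replicate 1, day 2 replicate 5 and day 3 replicate 4 of run set B have counts in 291, 260 and 80 genes.

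Day 10 against day 1 compares the latest with the earliest birds, and several interferon-inducible and chemokine genes were called lower at day 10. GVINP1, a very large interferon-inducible GTPase, averaged 3.74 ± 0.898 CPM at day 10 (SD, n = 6) and 38.9 ± 29.2 CPM at day 1 (n = 6), a log2 fold change of -3.38 (SE 0.398, adjusted p = 1.68e-05). GBP, a guanylate-binding protein of the interferon-gamma response, averaged 3.61 ± 1.19 CPM against 19.8 ± 13.8 CPM (log2 fold change -2.43, SE 0.337, adjusted p = 0.000301). Chemokine transcripts also fell, with CCL26 at 21.7 ± 5.55 against 79.6 ± 26.5 CPM (log2 fold change -1.88, adjusted p = 0.00364). CCL19, which draws T cells and dendritic cells into lymphoid zones, stood at -1.89 (adjusted p = 0.0215) and CCL4-2 at -1.80 (adjusted p = 0.0112). With the 12 birds left out in turn, CCL19 kept its call in 5 and CCL4-2 in 8. IRF1, the transcription factor that carries interferon-gamma signals to target genes, fell from 134 ± 46.9 to 69.5 ± 9.81 CPM (log2 fold change -0.96, SE 0.170, adjusted p = 0.0103).

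The test called 11 genes, 10 lower and 1 higher. The other lower genes were BATF3, a transcription factor of cross-presenting dendritic cells, at a log2 fold change of -1.26 (adjusted p = 0.0215), and the complement protease C1R at -0.84 (adjusted p = 0.0174). They also included the uncharacterised protein-coding genes LOC107055361 at -1.31 (adjusted p = 0.00289) and LOC420368 at -0.82 (adjusted p = 0.00387). MIR215, a microRNA gene, was the gene that rose, from 0.779 ± 0.215 to 1.76 ± 0.503 CPM (log2 fold change 1.13, adjusted p = 0.0273). It kept its call in 9 of 14 settings and with 4 of the 12 birds left out in turn, and the total of 11 genes became 4 to 26 with a bird left out. GVINP1, GBP and CCL26 are named by the fixed rule or by the list tests or both, and BATF3, C1R, CCL4-2, MIR215 and both uncharacterised genes were chosen after their values were seen. An unadjusted p under 0.05 was reached by 1174 genes, where chance gives 962 in each comparison, and DESeq2 called 90 genes, 57 higher and 33 lower. Of the other comparisons, day 2 against day 1 and day 10 against day 3 of run set B lay above 962, and the remaining 6 lay below it, at 435 to 807. In the fit of these 2 groups alone, 3 genes were called, and with the ribosomal RNA percent as a covariate the count was 107, with 78 higher and 29 lower. With a surrogate variable 110 were higher and 50 lower.

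**Figure D3:**
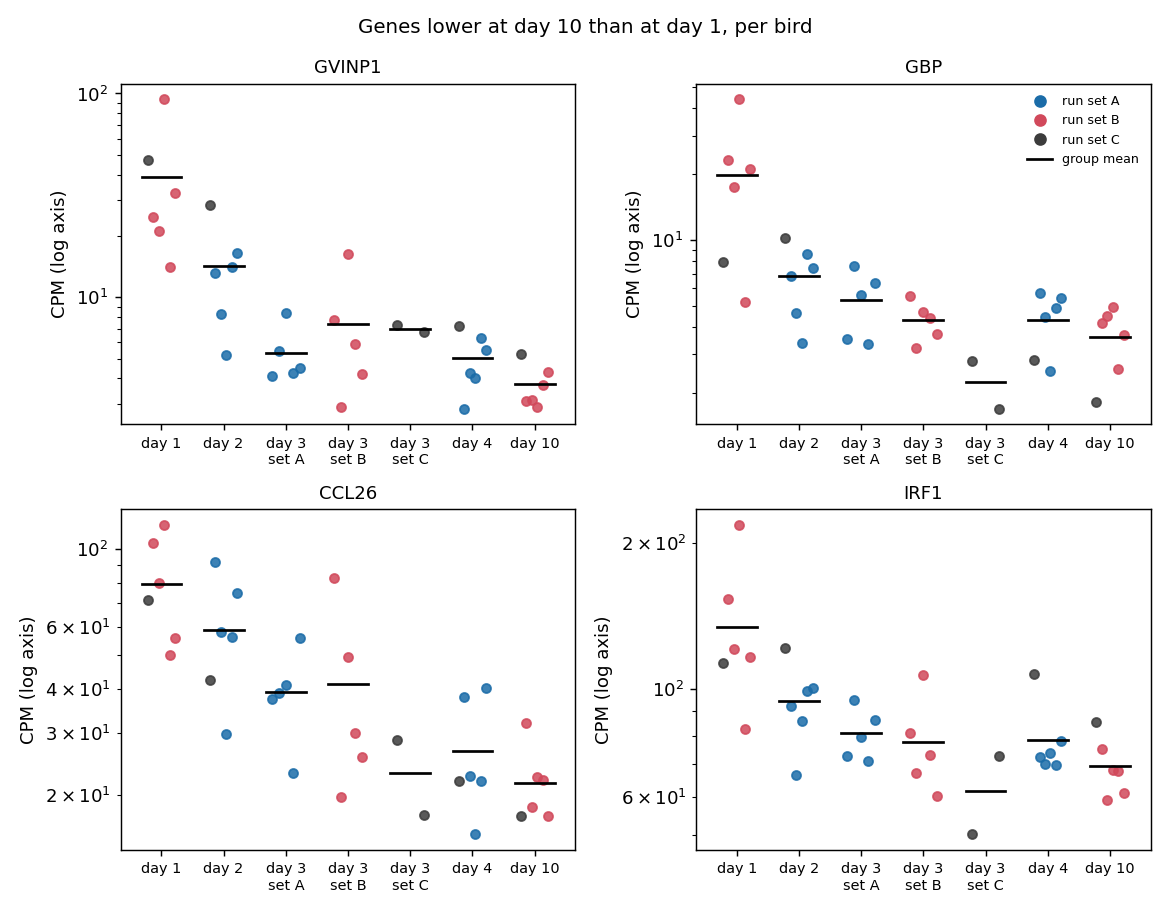
CPM of GVINP1, GBP, CCL26 and IRF1 per bird by group on log axes, with points coloured by run set and bars for group means. GVINP1 lies between 14.1 and 93.8 CPM in the day 1 birds and between 2.91 and 5.25 CPM in the day 10 birds.

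Of the 27 gene lists, 9 passed at day 10 against day 1, all toward lower values. With the ribosomal RNA percent as a covariate 2 passed, and without day 1 replicate 4 the count was 4. Of the 18 tested genes of the interferon-gamma response, 15 lay below 0 (median log2 fold change -0.46, adjusted p = 3.74e-08; adjusted p = 0.421 with an estimated correlation). GBP and IRF1 were the 2 members called over all genes, and 9 were called when adjusted over the list alone. IRF8, a factor of myeloid cells in that list, had a log2 fold change of -0.56 (adjusted p = 0.0788; 0.000917 by DESeq2). Cytotoxic and NK cell genes had 11 of 12 members below 0 (median -0.34, adjusted p = 0.000447; adjusted p = 0.579 with an estimated correlation). Of these, 0 were called over all genes and 3 adjusted over the list alone. Among them the granzyme GZMA differed by -1.31 (adjusted p = 0.304), the antimicrobial granulysin GNLY by -0.69 (adjusted p = 0.52) and FASLG by -0.58 (adjusted p = 0.568). All 19 T cell markers lay below 0 (median -0.27, adjusted p = 0.00424; adjusted p = 0.965 with an estimated correlation). LCK stood at -0.59, CD28 at -0.57 and CD8A at -0.52, each uncalled.

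Inflammatory cytokines and chemokines had 17 of 21 members below 0, with 1 called over all genes and 2 adjusted over the list alone (adjusted p = 0.00742; adjusted p = 0.579 with an estimated correlation). CCL20, the exception in direction among its leading members, stood at 0.59 (adjusted p = 0.867), and CCL4 at -0.94 (adjusted p = 0.373). Cholesterol synthesis genes had 20 of 21 members below 0 (adjusted p = 0.000655; adjusted p = 0.965 with an estimated correlation). Among them were FDFT1, which makes squalene, at -0.65, and LSS at -0.37. Cell division genes had 22 of 23 below 0 (adjusted p = 0.00805; adjusted p = 0.965 with an estimated correlation). CCNB3 stood at -0.57, TOP2A at -0.44 and MCM5 at -0.44. MHC class I presentation passed with 9 of 10 members below 0 and 1 called adjusted over the list alone (adjusted p = 0.0147; adjusted p = 0.579 with an estimated correlation). T cell inhibition and regulation passed with 11 of 13 below 0 and 2 called adjusted over the list alone (adjusted p = 0.0101; adjusted p = 0.655 with an estimated correlation). The type I interferon response had 18 of 22 below 0 (adjusted p = 0.0403; adjusted p = 0.965 with an estimated correlation). In the lists for which no such count is given, 0 members were called adjusted over the list alone.

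Of the 13 genes followed in advance, 0 were called by edgeR at day 10 against day 1. IFNG itself was near the floor, at 0.0750 ± 0.0597 CPM at day 10 and 0.296 ± 0.217 CPM at day 1 (log2 fold change -2.03, SE 0.642, adjusted p = 0.401). IL10 averaged 0.00717 and 0.141 CPM (log2 fold change -3.44, adjusted p = 0.148; called by DESeq2 at -3.35 and an adjusted p = 0.00939), and the inducible nitric oxide synthase NOS2 averaged 7.83 and 15.8 CPM (log2 fold change -1.0, adjusted p = 0.645). IL22 differed by -1.08, IL17A by -0.28, IL1B by 0.41 and the joining chain JCHAIN of secreted antibodies by 0.41. The mucin MUC2 differed by -0.17, the fatty acid binding protein FABP2 by 0.20, the macrophage receptor CSF1R by 0.12 and MKI67 by -0.18. The adjusted p of these 8 lay between 0.883 and 1. Without day 1 replicate 4, which had the highest NOS2, NOS2 stood at -0.42 and IL22 at -0.31. IL17A ranged from -1.89 without day 10 replicate 5 to -0.0363 without day 10 replicate 3.

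GBP and GVINP1 were also lower in the day 3 birds of run set B than at day 1, where 5 birds lie in run set B and 1 in run set C. GBP averaged 4.31 ± 0.902 CPM at day 3 (SD, n = 5) against 19.8 ± 13.8 CPM at day 1 (n = 6), a log2 fold change of -2.34 (SE 0.362, adjusted p = 0.0053). GVINP1 averaged 7.38 ± 5.28 against 38.9 ± 29.2 CPM (log2 fold change -2.31, SE 0.409, adjusted p = 0.0273). These 2 were the only genes called, beside 510 at an unadjusted p under 0.05 and 4 by DESeq2. With replicate number as a block in the fit of all birds, 2 genes were called as well (log2 fold change -2.27 for GBP and -2.28 for GVINP1, both at an adjusted p = 0.0136). That block gives each number an effect common to all groups. It is therefore not a paired test of these birds, and none was run for genes. Without day 3 replicate 3, or without day 3 replicate 6, 0 genes were called, and in the fit of both groups alone 0 genes were called. GVINP1 kept its call with 6 of the 11 birds left out in turn and in 12 of 15 settings, with a log2 fold change of -1.70 (adjusted p = 0.275) without day 1 replicate 4.

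The interferon-gamma response had 17 of 18 members below 0 in these birds (median log2 fold change -0.51, adjusted p = 1.55e-13; adjusted p = 0.0681 with an estimated correlation). Of these, 1 was called over all genes and 8 adjusted over the list alone. IRF1 stood at -0.78 (adjusted p = 0.466) and LYGL, a lysozyme of the goose type, at -2.41 (adjusted p = 0.914). All 22 genes of the type I interferon response lay below 0 (median -0.31, adjusted p = 8.22e-07; adjusted p = 0.491 with an estimated correlation). Among them were SAMD9L at -1.68, EPSTI1 at -0.71 and the RNA sensor IFIH1 at -0.66, each uncalled. T cell inhibition and regulation had 13 of 13 below 0 and 2 called adjusted over the list alone (adjusted p = 0.00025; adjusted p = 0.464 with an estimated correlation). SOCS1 stood at -0.72, IL10 at -3.08 and CD274 at -0.50. T cell markers had 18 of 19 below 0 (adjusted p = 0.00586; adjusted p = 0.889 with an estimated correlation). CD2 stood at -0.28, CD28 at -0.39 and THEMIS at -0.53. Cell division genes had 21 of 23 below 0 (adjusted p = 0.00633; adjusted p = 0.895 with an estimated correlation). CCNB3 stood at -0.32, CENPF at -0.47 and BUB1B at -0.37. Cytokines and chemokines had 12 of 21 below 0 and 1 called adjusted over the list alone (adjusted p = 0.033; adjusted p = 0.889 with an estimated correlation). CCL19 stood at -1.82 (adjusted p = 0.223), IL8L2 at -0.90 and IL22 at -1.25. Several of these gene values rested on day 1 replicate 4. Without this bird LYGL stood at -1.45, CD274 at -0.20, THEMIS at -0.21, IL8L2 at -0.33 and IL22 at -0.38. The interferon-gamma list still passed without it by camera with the preset correlation (adjusted p = 1.59e-07). Other values moved with other birds. Without day 3 replicate 2 CENPF stood at -0.28 and BUB1B at -0.20, and without day 1 replicate 2 CD28 stood at -0.20. In the type I interferon, T cell marker and cell division lists, 0 members were called adjusted over the list alone.

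From day 3 of run set B to day 10, edgeR called 0 genes, with 1306 at an unadjusted p under 0.05, and DESeq2 called 14. The interferon-gamma list had 10 members above and 8 below 0 (adjusted p = 0.911), and 0 of the 27 lists passed.

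Day 4 against day 2 brackets the first days after entry of the parasite, and no single chicken gene was called. edgeR called 0 genes, with 435 at an unadjusted p under 0.05, and DESeq2 called 3. Of the 27 lists 10 passed, among them interferon-gamma, T cell, macrophage, cell division and sterol genes toward lower values at day 4 and epithelial junction genes toward higher values. All 18 members of the interferon-gamma response lay below 0 (median log2 fold change -0.29, adjusted p = 7.74e-09; adjusted p = 0.183 with an estimated correlation). Of these, 0 were called over all genes and 1 adjusted over the list alone. LYGL averaged 3.17 ± 2.12 CPM at day 4 (SD, n = 6) and 13.2 ± 11 CPM at day 2 (n = 6), a log2 fold change of -2.05 (SE 0.561). IFNG differed by -1.35 and IRF8 by -0.28, and all 3 had an adjusted p of 1.

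All 23 cell division genes lay below 0 (median -0.37, adjusted p = 1.06e-09; adjusted p = 0.312 with an estimated correlation). CCNB3 stood at -0.57, BIRC5 at -0.49 and CCNB2 at -0.48. Of the 21 cholesterol synthesis genes 20 lay below 0 (adjusted p = 3.39e-08; adjusted p = 0.312 with an estimated correlation). FDPS stood at -0.55, FDFT1 at -0.50 and ACAT2 at -0.39. Macrophage and dendritic cell markers had 16 of 20 below 0 (adjusted p = 5.31e-05; adjusted p = 0.256 with an estimated correlation). Among them were FLT3 at -0.62, the chemokine receptor XCR1 at -0.54 and the complement gene C1QB at -0.33. All 19 T cell markers lay below 0 (adjusted p = 5.31e-05; adjusted p = 0.447 with an estimated correlation). CD4 stood at -0.43, CD3D at -0.35 and THEMIS at -0.44. Epithelial junction genes had 17 of 19 above 0 (median 0.28, adjusted p = 6.21e-05; adjusted p = 0.178 with an estimated correlation). CDH1, the adhesion molecule of epithelial cells, averaged 948 ± 413 CPM at day 4 and 660 ± 141 CPM at day 2 (log2 fold change 0.51, SE 0.292). CGN and OCLN of the tight junction stood at 0.39 and 0.52. In these 6 leading lists 1 member was called adjusted over the list alone. Also passing toward lower values were T cell inhibition and regulation (adjusted p = 0.00143; adjusted p = 0.312 with an estimated correlation) and oxidative defence and metal binding (adjusted p = 0.0267; adjusted p = 0.256 with an estimated correlation). So were inflammatory cytokines and chemokines (adjusted p = 0.0331; adjusted p = 0.447 with an estimated correlation) and heterophil genes (adjusted p = 0.0384; adjusted p = 0.312 with an estimated correlation).

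Of the other genes followed in advance, NOS2 differed by -0.77 between day 4 and day 2, JCHAIN by -0.50, IL22 by -0.56, IL17A by -0.58, MUC2 by -0.34, MKI67 by -0.30, GNLY by -0.20 and CD8A by -0.11. FABP2 differed by 0.58, IL1B by 0.34, IL10 by 0.14 and CSF1R by 0.09, each with an adjusted p of 1.

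The day 3 birds of run set A were compared with day 2 and day 4, which each hold 5 birds of run set A and 1 of run set C. In the comparison with day 2, 3 lists passed, all toward lower values at day 3. Without run set C, without day 2 replicate 1 or without day 3 replicate 5, 1 list passed. Against day 2, edgeR called 0 genes, with 618 at an unadjusted p under 0.05, and DESeq2 called 0. Cholesterol synthesis genes had 18 of 21 members below 0 (median -0.47, adjusted p = 3.22e-06; adjusted p = 0.96 with an estimated correlation). MSMO1 stood at -0.87, STARD4 at -0.63 and ACAT2 at -0.61. Cell division genes had 19 of 23 below 0 (adjusted p = 0.0149; adjusted p = 0.96 with an estimated correlation). AURKA stood at -0.89 and CDK1 at -0.62, whereas the replication licensing gene MCM2 stood at 0.43. The interferon-gamma response had 14 of 18 below 0 (adjusted p = 0.0368; adjusted p = 0.96 with an estimated correlation). NOS2 stood at -1.02, WARS at -0.59 and IRF8 at -0.20. This list no longer passed without run set C (adjusted p = 0.0757) and passed with only 5 of the 11 birds left out in turn (adjusted p up to 0.178). In these 3 lists 0 members were called adjusted over the list alone.

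Between day 3 of run set A and day 4, 3 lists passed with the preset correlation, all toward lower values at day 4. edgeR called 0 genes, with 497 at an unadjusted p under 0.05, and DESeq2 called 0. MARCO, a scavenger receptor of macrophages, averaged 30.8 ± 8.82 CPM at day 4 (SD, n = 6) and 56.8 ± 6.91 CPM at day 3 (n = 5), a log2 fold change of -0.95 (SE 0.241). It was the only gene of the 3 lists below called adjusted over the list alone, and over all genes its adjusted p was 0.995. Macrophage and dendritic cell markers had 15 of 20 below 0 (adjusted p = 0.000127; adjusted p = 0.698 with an estimated correlation), with C1QC at -0.37 and C1QB at -0.32. T cell markers had 17 of 19 below 0 (adjusted p = 3.28e-05; adjusted p = 0.698 with an estimated correlation). CD8A stood at -0.52, LCK at -0.50 and CD8B at -0.46. MHC class II presentation had 9 of 11 below 0 (adjusted p = 0.0186; adjusted p = 0.698 with an estimated correlation). BLB1 stood at -0.59, DMB2 at -0.37 and CD74 at -0.29. IFNG stood at -0.63, IL17A at -0.74, IL22 at -0.34, IL10 at -0.30, GNLY at -0.23, CSF1R at -0.15 and MUC2 at -0.01. IL1B was at 0.08, JCHAIN at 0.17, NOS2 at 0.25, MKI67 at 0.27 and FABP2 at 0.27. The adjusted p of these genes was 0.995 to 0.999.

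The comparisons across run sets rest on the single birds of days 1, 2, 4 and 10 in run set C and had standard errors of about 0.34 to 0.39. For day 2 against day 1, edgeR called 0 genes, with 1173 at an unadjusted p under 0.05, and DESeq2 called 33. Oxidative phosphorylation genes were the single list that passed, with 19 of 23 members above 0 and 0 called adjusted over the list alone (median 0.36, adjusted p = 2.75e-05; adjusted p = 0.99 with an estimated correlation). NDUFA4 of the respiratory chain stood at 0.94, COX4I1 at 0.89 and COX6C at 0.85, and without the run set term at 0.41, 0.36 and 0.34. With the ribosomal RNA percent as a covariate 0 lists passed.

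For day 10 against day 4, edgeR called 0 genes, with 653 at an unadjusted p under 0.05, and DESeq2 called 2. All 22 genes of the type I interferon response lay below 0 (median -0.41, adjusted p = 0.000343; adjusted p = 0.888 with an estimated correlation). IFIT5 stood at -1.06, IFI27L2 at -0.76 and ADAR at -0.32. Oxidative phosphorylation genes had 22 of 23 below 0 (adjusted p = 0.000755; adjusted p = 0.888 with an estimated correlation). NDUFA4 stood at -0.80, COX4I1 at -0.70 and COX6C at -0.66. The interferon-gamma response had 15 of 18 below 0 (adjusted p = 0.0391; adjusted p = 0.888 with an estimated correlation). GBP stood at -1.50, SOCS1 at -0.62 and IRF1 at -0.53, and 0 members of these lists were called adjusted over the list alone. IL10 stood at -1.89, IFNG at -1.34, FABP2 at -1.21, IL17A at -0.65, IL22 at -0.51, MUC2 at -0.50, NOS2 at -0.30, GNLY at -0.24 and CSF1R at -0.17. IL1B was at 0.05, JCHAIN at 0.29, CD8A at 0.36 and MKI67 at 0.36, and each of these 13 had an adjusted p of 1. These fitted values are net of a run set effect estimated from run set C, and for some genes the measured levels differed less or the other way: IFNG averaged 0.0750 CPM at day 10 and 0.0628 at day 4, MKI67 48.9 and 53.6 CPM and GBP 3.61 and 4.30 CPM. With birds left out in turn, IL10 ranged from -2.93 to -1.03, FABP2 from -1.58 to -0.446 and GNLY from -0.933 to -0.081. Without the run set term 0 lists passed. The interferon-gamma list passed in 2 of 6 other settings and with 5 of the 12 birds left out in turn (adjusted p up to 0.27 without day 4 replicate 1).

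The day 3 birds of the 2 larger sets carry the same day label. Their fitted difference is net of a run set effect, so it is not the difference of the measured levels. That effect is estimated from the single birds of days 1, 2, 4 and 10 in run set C. A single gene was called, LOC112530044, annotated as a small nucleolar RNA (log2 fold change 4.05, SE 0.683, adjusted p = 0.0246), beside 807 genes at an unadjusted p under 0.05 and 23 called by DESeq2. It averaged 5.28 ± 1.66 CPM in run set A (SD, n = 5) and 3.99 ± 1.49 CPM in run set B (n = 5), so that the fitted fold change stems from the run set term. Without that term it was 0.41. LOC112530044 lost its call without replicate 3 or 5 of run set A (adjusted p = 0.0795 and 0.0624) or without replicate 4, 5 or 6 of run set B (adjusted p = 0.0613, 0.058 and 0.0657).

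In the fit with the run set term 6 lists passed, all toward higher values in run set A. The type I interferon response had 21 of 22 members above 0 (median 0.71, adjusted p = 2.06e-05), with IFI6 at 2.51, IFIT5 at 2.17 and IFI27L2 at 1.15. The interferon-gamma response had 14 of 18 (adjusted p = 0.00274), with LYGL at 3.18, GBP at 1.72 and SOCS1 at 0.89. Red blood cell genes had 8 of 10 above 0 and 1 called adjusted over the list alone (adjusted p = 0.0257), with the globins HBBA at 2.68 and HBA1 at 2.13. TSPO2, the third, was near the floor (0.0277 and 0.00957 CPM). Oxidative phosphorylation genes had 19 of 23 above 0 (adjusted p = 0.000532), with COX5A at 1.01, NDUFA4 at 0.75 and COX6C at 0.73. The measured levels did not show this, with COX5A at 27.8 CPM in run set A and 31.8 CPM in run set B, NDUFA4 at 27.6 and 26.9 CPM and COX6C at 171 and 164 CPM. T cell inhibition and regulation had 11 of 13 above 0 and MHC class II presentation 11 of 11 (both at an adjusted p = 0.0495, with 0 members of these or the other lists called over all genes). IL10 stood at 1.83, BTLA at 0.67, BLB1 at 0.89, IFI30 at 0.55 and RFXAP at 0.45. With an estimated correlation all 6 had an adjusted p = 0.875, and with the ribosomal RNA percent as a covariate 0 lists passed. Without the run set term, type I interferon (adjusted p = 0.00244), red blood cell and T cell inhibition genes (both 0.000465) also passed toward higher values in run set A. Interferon-gamma (0.0785), MHC class II (0.204) and oxidative phosphorylation genes (0.239) did not. T cell markers passed as well (0.000465), and cholesterol synthesis (1.04e-07), enterocyte (0.00142) and lipid absorption genes (0.0297) passed toward lower values. The values without the run set term are given at the preset correlation only.

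**Figure D4:**
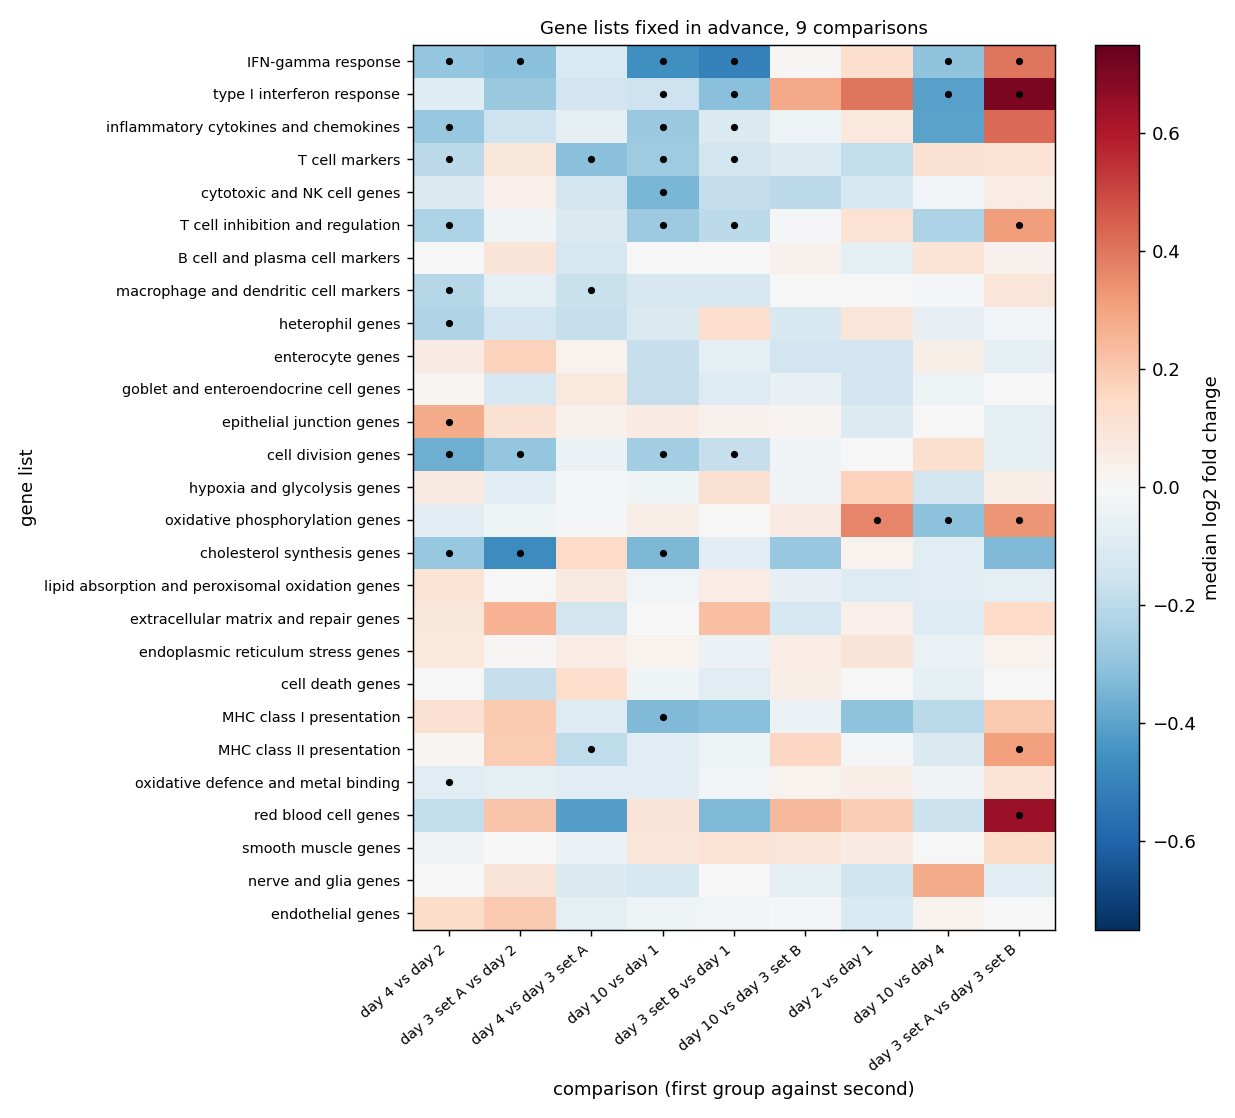
Median log2 fold change of the tested members of each of the 27 gene lists (lines) in each of the 9 comparisons (columns), from blue for lower to red for higher in the first group. Black dots mark an adjusted p under 0.05 by camera with a preset correlation of 0.01. Interferon-gamma genes are lower in 5 of the comparisons with a dot and higher in 1, and 0 dots remain with an estimated correlation.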

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

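The tests of the 4 leading parasite genes, of the cell type markers, of the ribosomal RNA covariate, of accidental pairing and of the splits that part pairs were chosen after the result was seen. A bird was singled out when its gap to the nearest bird of its group was large against the range of the group, by Dixon's ratio at 95%. This was met by 12 of 90 groups, where chance gives about 4.5, or 1 in 20.

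Parasite counts were 0.521 to 4.37 CPM per bird, although all are labelled as infected. The parasite share without its leading gene was not higher at day 4 than at day 2 (difference of the mean log2 share -0.96, SE 0.685, n = 6 each), and it was -0.45 (SE 0.522) without day 2 replicate 1, which carried much of it. Both values lie below a doubling of this share by more than their SE. They set no bound on the parasite population itself, because the origin of these counts is open. Reads of chicken ribosomal RNA assigned to parasite genes remain open, since the share and the ribosomal RNA percent had a Spearman rho of 0.252 within run sets and a Pearson r of 0.204 (permutation p = 0.153 and 0.293, adjusted p = 0.459 and 0.777 over 3 relations). The r was 0.142 without the 2 birds farthest on ribosomal RNA. Within run sets A and B rho was 0.164 and 0.193 and r was 0.0799 and 0.0802. A collection of reads of other origin by a few genes also remains open, as the 4 leading genes held 73% of the counts, short of a share that would decide. That pooled share mixes unlike birds. The leading gene alone held 17.4% and 26.4% in day 2 replicates 1 and 5 and 13.4% in day 3 replicate 4 of run set B. It held 46.1% to 82.1% in each other bird. The polyA selection, an infection that did not take or had little parasite RNA at these times, and sampling of tissue away from the parasite were not tested, and there were no uninfected birds to give a background.

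The 10 genes lower at day 10 than at day 1 had a median log2 fold change of -1.55. It was -1.62 without run set C, so that set does not explain it. With the ribosomal RNA percent of each bird as a covariate it was -1.69, which argues against a linear effect of ribosomal RNA common to all groups. Within run set B the day 10 and day 1 birds did not overlap in that percent, so other effects of it are not excluded. The lowest median of the T cell, NK cell and macrophage marker lists was -0.34 (interquartile range -0.54 to -0.25). This argues against a loss of these cells as a whole that is as large as the fall of the 10 genes. The 10 genes were picked for their fall in these birds, however, and the T cell list also lay below 0 (median -0.27). A smaller loss, or a loss of only some of these cells, remains open. CSF1R averaged 62.5 and 67.8 CPM at day 1 and day 10 and CD8A 17.0 and 11.7 CPM. With 0 birds labelled as uninfected, the time after infection cannot be told apart from the age of the bird or from the handling on day 1.

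Day 1 and day 3 birds of run set B with the same replicate number deviated together from their group means over 8494 genes, with a mean correlation of 0.604. Of the 120 ways to pair them, 1 (the numbering itself) reached this value, and the next stood at 0.46. These birds were picked for their correlation among 9 comparisons, and the share adjusted over these was 0.075, so an accident remains open. After regression on the ribosomal RNA percent the mean correlation was 0.549, so that share does not account for it, although 2 of the 120 pairings were then as high. A shared pen, position on a plate or order of extraction could give such pairs, and none of these is stated in the labels.

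The remaining birds that stood apart are given as values. Replicate 1 of days 2, 4 and 10 is the only bird of its group in run set C. Gaps of these birds cannot be told apart from a run set difference. In the fit of all birds, 2248 of 19243 genes were called between run sets C and A. For parasite counts as CPM, day 2 replicate 1 had 4.14 (next 1.77) and day 3 replicate 4 of run set A had 0.875 (next 1.01). Day 3 replicate 4 of run set B had counts in 80 parasite genes (next 14). Ribosomal RNA took 7.89% in day 10 replicate 1 (next 44.2%). CCL26 was at 32.0 CPM in day 10 replicate 2 (next 22.5) and IRF1 at 107 CPM in day 4 replicate 1 (next 78.2). Day 1 replicate 4 had BATF3 at 13.2 CPM (next 6.59) and C1R at 40.5 CPM (next 26.6), and day 3 replicate 4 of run set A had C1R at 23.7 CPM (next 16.4). LOC107055361 was at 5.91 CPM in day 10 replicate 1 (next 8.03), LOC420368 at 26.3 CPM in day 4 replicate 1 (next 34.7) and LOC112530044 at 0.289 CPM in day 10 replicate 1 (next 6.97).

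Other splits of the same birds into groups of the same sizes were drawn for each comparison, 60 with the real split included. For genes at day 10 against day 1, 2 of 60 splits, the real split among them, gave at least the real 11 genes. The highest other gave 41 and exchanged day 1 replicate 5 with day 10 replicate 4. This met the limit set in advance for a single comparison. It was not adjusted over the 9 comparisons, so chance is not excluded. For day 3 of run set B against day 1, the real split was set against all 32 splits that part the 5 pairs by number, as the labels do. Of the 32, 1, the real split, gave at least 2 genes (highest other 1), the smallest share such splits can give. The count was 0 without day 3 replicate 3 or 6. These splits were chosen after the result was seen and rest on a pairing that may be an accident. Chance is therefore not excluded there either. Among the 60 splits drawn without regard to pairs, those that parted fewer pairs gave up to 6 genes and 16 lists. Chance cannot be excluded for the 2 day 3 sets (5 splits, real 1, highest other 2791). In the comparisons across run sets, the other splits drawn mix birds of run sets A and B within a group. The real split does not, and it is estimated only through run set C. Its counts are therefore not comparable with those of the other splits, which cannot decide there. For the comparisons with 0 genes every split gives as many, so the splits decide nothing there. Their highest other count was 2 for day 4 against day 2, 1 for day 3 of run set A against day 2, 520 for day 4 against day 3 of run set A, 1 for day 10 against day 3 of run set B, 0 for day 2 against day 1 and 1 for day 10 against day 4. The splits with 2791 and 520 genes point to a structure of the samples other than the groups. For lists, chance cannot be excluded in any comparison with a list that passed. As many lists came from 19 splits for day 4 against day 2 (real 10, highest other 15), 55 for day 3 of run set A against day 2 (3 and 15), and 52 for day 4 against day 3 of run set A (3 and 13). They came from 7 splits for day 10 against day 1 (9 and 10) and 12 of the 32 for day 3 of run set B against day 1 (6 and 9). Day 10 against day 3 of run set B had 0 lists (highest other 16), so its splits decide nothing. As many came from 54 splits for day 2 against day 1 (1 and 12), 43 for day 10 against day 4 (3 and 8) and 37 for the day 3 sets (6 and 17). These comparisons cross run sets, so their other splits are not like the real split for lists either.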

How the results depend on the processing

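The alternatives on ribosomal RNA, the surrogate variable, the robust fit, the list tests that left out a bird and the share without the leading parasite gene were chosen after the data were seen. All 10 genes lower at day 10 than at day 1 stayed lower under every alternative tried, with a median log2 fold change of -1.69 to -1.36. GVINP1 and CCL26 stayed called under all 14 settings and with each of the 12 birds left out. GBP and LOC107055361 lost the call in 1 of the 14 settings and kept it with every bird left out. With the 12 birds left out in turn, LOC420368 kept it in 10, IRF1 and CCL4-2 in 8, BATF3 in 7, C1R in 6, CCL19 in 5 and MIR215 in 4. Of the 14 settings, LOC420368 kept it in 13, IRF1, CCL19 and CCL4-2 in 12, C1R in 10 and BATF3 and MIR215 in 9, with adjusted p up to 0.541. Other named genes gained a call there: IRF8 in 4 settings and without day 1 replicate 5, IL10 with DESeq2 and a surrogate variable (adjusted p = 0.00939 and 0.0462), FASLG with DESeq2 (0.0422) and GZMA with a surrogate variable (0.0377). At day 3 of run set B against day 1, CCL19 gained it with DESeq2 (0.00711) and, with IRF1, without day 1 replicate 5 (both 0.0393). Of 2187 values of named genes under other settings, 2125 kept direction and side of the threshold, and of 1823 with a bird left out, 1748 did. Only 14 of the 159 named genes by comparison were called in the main fit. Most of these values are thus uncalled genes that stayed uncalled, and they say little about how firm the calls are. The median log2 fold change over all genes lay between -0.0847 and 0.0768 in every setting and comparison. The cause of the changes below was not tested, except that fits of the 2 compared groups alone, or without birds, hold fewer birds, and that DESeq2 is another test. The parasite share was limited by its 18 to 1955 counts per bird. The comparisons across run sets were limited by the single birds of days 1, 2, 4 and 10 in run set C. The 2 day 3 sets could not be compared without run set C, in a fit of those groups alone or as a pooled group. Day 2 against day 1 and day 10 against day 4 could not be compared without run set C. The alternatives of the tests of single parasite genes and of load were not run.

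At day 10 against day 1 the main count was 11. It was 90 with DESeq2, 17 with at least 1 CPM in at least 6 birds, and 17 with the replicate block. It was 107 with the ribosomal RNA percent as a covariate, 5 without birds over 50% ribosomal RNA, 160 with a surrogate variable and 3 in the fit of both groups alone. Leaving out single birds gave 4 to 26 genes: 5 without day 1 replicate 4 or day 10 replicate 3, 4 without day 10 replicate 5 or 6, and 26 without day 10 replicate 4. For day 3 of run set B against day 1 (main 2) the count was 4 with DESeq2, 1 without run set C, 1 without birds over 50% ribosomal RNA, 4 with a surrogate variable and 0 in the fit of both groups alone. Single birds left out gave 0 to 6 (6 without day 1 replicate 5, 1 without day 1 replicate 4 or day 3 replicate 2 or 5, 0 without day 3 replicate 3 or 6). GVINP1 lost its call without run set C (adjusted p = 0.0706), without birds over 50% ribosomal RNA (0.0881), without day 1 replicate 4 (0.275) and without day 3 replicate 2, 3, 5 or 6 (0.126 to 0.221). GBP had an adjusted p of 0.0544 and 0.0538 without day 3 replicate 3 and 6, and up to 1 over the settings.

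In the comparisons with a main count of 0, DESeq2 gave 3 genes for day 4 against day 2, 14 for day 10 against day 3 of run set B, 33 for day 2 against day 1 and 2 for day 10 against day 4. Day 10 against day 3 of run set B gave 1 without run set C, 1 with all 12 day 3 birds as a group, 6 with a surrogate variable and 2 with the robust fit. It gave 0 to 2 with birds left out (2 without day 10 replicate 1, 1 without day 10 replicate 3 or day 3 replicate 3). Day 2 against day 1 gave 4 with the replicate block, 16 with a surrogate variable, 2 in the fit of both groups alone and 0 to 3 with birds left out (3 without day 1 replicate 6). Day 10 against day 4 gave 0 to 4 with birds left out (4 without day 10 replicate 1). The 2 day 3 sets (main 1) gave 23 with DESeq2, 0 without the run set term, 4 with the replicate block, and 0 with the first run of each bird. They gave 0 with the ribosomal RNA covariate, 0 without birds over 50% ribosomal RNA and 11 with a surrogate variable. With birds left out they gave 0 to 4 (0 without replicate 3 or 5 of run set A or 4, 5 or 6 of run set B, 3 without replicate 6 of run set A, 4 without replicate 3 of run set B).

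Of the lists, 0 passed with an estimated correlation and 0 with fry in each of the comparisons. Beyond that, day 10 against day 1 (main 9) gave 2 with the ribosomal RNA covariate and 4 to 11 with birds left out (4 without day 1 replicate 4). Day 10 against day 3 of run set B (main 0) gave 0 to 3 with birds left out (3 without day 3 replicate 2, 2 without day 3 replicate 3 or 4, 1 without day 10 replicate 4 or 6). Day 10 against day 4 (main 3) gave 0 without the run set term. Day 2 against day 1 (main 1) gave 2 without the run set term, 0 with the ribosomal RNA covariate and 1 to 5 with birds left out (5 without day 1 replicate 1, 2 without day 2 replicate 1). Day 3 of run set A against day 2 (main 3) gave 1 without run set C and 1 to 6 with birds left out (1 without day 2 replicate 1 or day 3 replicate 5, 6 without day 3 replicate 6). Day 4 against day 3 of run set A (main 3) gave 5 without run set C, 8 with the ribosomal RNA covariate and 9 with a surrogate variable. It gave 3 to 10 with birds left out (10 without day 3 replicate 6, 7 without day 4 replicate 6, 6 without day 3 replicate 2, 5 without day 3 replicate 3 or 5 or day 4 replicate 1). The day 3 sets (main 6) gave 0 with the ribosomal RNA covariate, 3 without birds over 50% ribosomal RNA, and 3 with a surrogate variable. They gave 2 to 8 with birds left out (2 without replicate 3 of run set B, 3 without replicate 3 or 4 of run set A or 5 or 6 of run set B).

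The parasite share at day 10 against day 1 (main 0.09) was -0.25 without the leading gene and -0.17 to 0.31 with birds left out. Day 2 against day 1 (main -0.08) was 0.18 without the leading gene and -0.43 to 0.14 with birds left out. Day 3 of run set A against day 2 (main -0.34) was 0.01 (0.00814) without run set C and with pairs by number, and -0.55 to 0.00814 with birds left out.

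Every named gene that changed sign was uncalled in the fit of all birds. For day 4 against day 3 of run set A, MUC2 (main -0.0104) stood at 0.134 without the run set term, 0.0672 with the replicate block, and 0.204 with all day 3 birds as a group. MUC2 stood at 0.0888 with the ribosomal RNA covariate, 0.00219 without birds over 50% ribosomal RNA, 0.0717 with a surrogate variable, 0.00939 in the fit of both groups alone and -0.252 to 0.219 with birds left out. IL10 was 0.248 and MKI67 -0.108 with all day 3 birds as a group. With birds left out, MKI67 ranged from -0.023 to 0.493, IL1B from -0.148 to 0.176, IL22 from -0.639 to 0.335, JCHAIN from -0.0646 to 0.252 and NOS2 from -0.0291 to 0.511. For day 4 against day 2, IL10 was -0.103 without run set C, -0.113 without birds over 50% ribosomal RNA and -0.103 to 0.289 with birds left out, and CSF1R ranged from -0.01 to 0.152. For day 10 against day 1, MKI67 was 0.0202 without run set C, 0.0424 with the ribosomal RNA covariate and -0.307 to 0.0192 with birds left out. For day 10 against day 4, IFNG was 0.206, MKI67 -0.131 and IL1B -0.0403 without the run set term, and IL1B was -0.0206 with the first run of each bird. GNLY was 0.025, JCHAIN -0.0298 and IL1B -0.0445 in the fit of both groups alone. With birds left out there, IL1B ranged from -0.179 to 0.368, IL22 from -1.45 to 0.197, MKI67 from -0.0531 to 0.937 and CD8A from -0.744 to 1.11. For the day 3 sets, COX5A was -0.191 without the run set term and IFI30 -0.552 with the ribosomal RNA covariate.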

Other observations

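The test of 10 genes over days 2 to 4, the overlap of the 3 fits, the division of the day 1 birds and the thinning of parasite counts were chosen after the results were seen.

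The 10 genes lower at day 10 than at day 1, among them GVINP1, GBP, CCL26, CCL19 and IRF1, were also followed over days 2 to 4 in the birds of run set A, none of which belong to day 1 or day 10. Their mean log2 CPM was 3.18 ± 0.202 at day 4 (SD, n = 5) and 3.90 ± 0.317 at day 2 (n = 5), a difference of -0.73 (exact permutation p = 0.00794, the smallest that 252 permutations can give). All 10 genes were lower at day 4. Whether the decline began at day 1 is not shown, since that step crosses run sets and the interferon-gamma list was not lower at day 2 than at day 1 in the fit with the run set term (adjusted p = 0.704, toward higher values). The following means are not a time course within one sequencing, as days 1 and 10 lie mainly in run set B and days 2 and 4 in run set A. Mean CPM of GVINP1 were 38.9 at day 1, 14.3 at day 2, 5.32, 7.38 and 7.01 at day 3 in run sets A, B and C, 5.03 at day 4 and 3.74 at day 10. Those of CCL26 were 79.6, 58.9, 39.2, 41.4, 23.0, 26.6 and 21.7.

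Of the 27 gene lists, 11 passed in no comparison of the fit of all birds with the run set term, although enterocyte and lipid absorption genes passed for the 2 day 3 sets without that term. Among them, extracellular matrix and repair genes came nearest at day 3 of run set B against day 1 (median 0.22, adjusted p = 0.0946). B cell and plasma cell markers (adjusted p = 0.105), goblet and enteroendocrine cell, endothelial and smooth muscle genes (each 0.219), cell death (0.23), lipid absorption and peroxisomal oxidation (0.233), enterocyte (0.337), nerve and glia (0.371), endoplasmic reticulum stress (0.438) and hypoxia and glycolysis genes (0.463) had these as their smallest adjusted p over the 9 comparisons.

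At day 10 against day 1, 37 genes were called by all 3 of DESeq2, the fit with the ribosomal RNA percent as a covariate and the fit with a surrogate variable. Of these, 27 were outside the main call, 22 higher and 5 lower. Among the lower were SOCS1, an inhibitor of interferon signalling (log2 fold change -0.77 in edgeR, adjusted p = 0.148), DUSP18 (log2 fold change -0.95 in edgeR, adjusted p = 0.198) and the immune-associated GTPase GIMAP1 (-0.78, adjusted p = 0.0573). Among the higher were CZH9ORF40 (0.46, adjusted p = 0.148) and EEF1E1 (0.52, adjusted p = 0.148).

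GBP and GVINP1 were lower both at day 10 and at day 3 of run set B, comparisons that share the day 1 birds. Independent lists of these sizes would share 0.00104 genes, and 12 simulations without any change shared 0 on average. Neither figure tests what the shared birds contribute. The first takes the lists as independent, and without any change hardly any gene could be called, so an overlap of 0 was nearly fixed. With the day 1 birds divided into sets of 3, a different set for each comparison, 1 and 0 genes were shared.

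Single birds differed in how widely their parasite counts were spread. Counts fell in 291 genes in day 2 replicate 1, 260 in day 2 replicate 5 and 80 in day 3 replicate 4 of run set B, and in 5 to 31 genes in each other bird. Thinned to 30 counts outside the leading gene, these birds had an expected 27.7, 27.6 and 26.1 genes, and the others with enough counts 5.22 to 19.9. Day 2 replicate 5 had counts in 197 and 76 genes in its 2 runs, and day 3 replicate 4 of run set B in 49 and 40.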
